A study of Mus musculus with 97 samples.

How the data were processed

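Nascent RNA was measured by TT-seq in ES-E14TG2a mouse embryonic stem cells after knockdown of 29 remodeler ATPases. Per the labels, cells were reverse transfected with esiRNA against the target or against green fluorescent protein as the control, and were given 4sU and harvested 48 hours later. RNA was extracted with TRIzol, ribosomal RNA was depleted with antisense oligonucleotides, and libraries were built with the NEBNext Ultra II RNA kit, also per the labels. The submitters' processing notes name cutadapt, Trimmomatic, STAR, SAMtools, featureCounts, DESeq2 and deepTools and the build mm10, with no versions and no order. The annotation used for counting, and whether counting used the strand, are not given in the sources used here, so values of genes that overlap another gene are uncertain. The report marks overlaps with protein-coding genes where it names a changed gene. Overlapped on the other strand by noncoding models, and so uncertain, are several targeted genes, Antxr1, Bcl2l14, Brdt, Cd44, Clca3b, Cubn, Dnah1, Fgf15, Gata6, Gbx2, Herpud1, Insc, Krt7, Mpzl3, Ncam1, Nkd2, Oas2, Pax6, Pkhd1, Pla2g7, Plb1, Plce1, Pou5f1, Slc5a4b, Slc7a11, Smc1b, Sox17, Spats2l, Sult6b1, Tbx3, Tmem132d, Ttll9 and Zfhx4.

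The main values are the authors' deposited raw counts of reads per feature, whole numbers with no normalization, over 85 libraries and 164310 features that hold 55433 genes and 4 classes of noncoding feature: DHSs between genes, DHSs inside genes, super-enhancers and promoter antisense regions. The last line of that table is incomplete and the feature on it was left out. A second deposited table holds batch-adjusted values that the authors made with ComBat-seq, per the file headers and name, for 183349 features. These are treated as a score and not as counts, because adjusting multiplied at least 1 library's count by over 1000 in 1147 features, 252 of them genes, and raised the column total to over 2 times the raw total in 10 libraries. The authors also deposited a batch number for each library, 22 batches in all, of which 17 hold 1 control library and 5 hold none. What a batch stands for is not given in the sources used here. Coordinates of noncoding features are those of the deposited feature list on mm10, and the score column of that list was not used here. Gene coordinates and overlaps come from GENCODE vM21 on GRCm38, the same assembly: 53569 of the 55433 gene names (96.6%) are in it, and 55182 of the 55271 DHSs listed as inside genes overlap a gene. Coordinates are 1-based. The 12 libraries of tagged lines depleted for 3 hours, which the labels also list among 97 samples, were not analysed here, so depletion was not compared with knockdown.

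Libraries were assigned to targets by their labels, with 1 exception: the third Smarcal1 library carries a number in the count tables that no label has, so it was taken as the remaining library of that target, with the batch of the remaining entry. The labels do not say that replicates were separate cultures beyond the words biological duplicate, so p-values measure only the spread between these samples. No library pair agreed within sampling noise, the lowest chi-square per degree of freedom between 2 libraries of a group being 8.56. No spike-in was used here, so a change of all transcription together cannot be seen, and each change is relative to the typical gene. Per library, 15500 to 19800 genes had at least 10 counts. The TMM factors ran from 0.588, in replicate 2 of the Chd1 knockdown, to 1.22.

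Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test) on the raw counts in 1 fit of all 85 libraries with a coefficient for each target and each batch, 51 coefficients and 34 residual degrees of freedom, plus a median of 17.31 prior degrees of freedom. Library sizes and TMM factors came from the genes. Features passed filterByExpr with a minimum count of 10, a minimum total of 15, a large group size of 10 and a proportion of 0.7, which kept 20714 genes and 22076 noncoding features. P-values were adjusted by Benjamini-Hochberg within the genes and within the noncoding features of each knockdown, and called below 0.05. Fitted log2 fold changes carry a prior count of 0.125. CPM were computed with TMM-scaled library sizes and are not adjusted for batch, so a CPM mean and a fold change can differ in size. With all groups in 1 fit, a target with no control in its batches is compared through the libraries of other targets that share them. Groups hold 2 or 3 libraries, so differences smaller than the spread between them were often not detectable at this depth and size. On simulated counts of 6000 genes, the fit recovered 58.2% of genes changed by a fold of 2 in the Chd4 comparison (n = 2), 92.4% at a fold of 4 and 16.4% at 1.5, with 4.31% false calls. For Smarca4 (n = 3) it recovered 73.1%, 90.9% and 31.3%, with 6.47% false calls.

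Named genes followed a rule set before the data were examined, as were the gene lists, the design and the alternatives unless said otherwise. For the main comparisons (Chd4, Chd8 and Hltf) it takes the 10 genes with the largest rise and the 10 with the largest fall among called genes with an average log2 CPM of at least 1, every knockdown library on the same side of its controls, and a symbol that is no numbered gene model. For the other 26 knockdowns it takes 3 in each direction, for noncoding features of the main comparisons 2, for each list up to 4 called members by absolute fold change, and 10 genes called in the most knockdowns. The side of a library was taken against the control of its batch, and where the batch holds none, from batch-adjusted log2 CPM against the mean of the adjusted controls. In each knockdown with up to 5 calls, those outside the rule are named as chosen after their values were seen. Some genes that the rule picks are not reported here.

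The 23 gene lists were naive pluripotency, formative and primed epiblast, 2-cell-like, mesoderm and primitive streak, endoderm, neuroectoderm, trophectoderm, Hox genes, germline genes silenced by DNA methylation, imprinted genes, p53 targets, interferon-stimulated genes, immediate early genes, heat shock, the integrated stress and unfolded protein responses, cholesterol biosynthesis, glycolysis and hypoxia, ribosomal proteins, ribosome biogenesis, replication-dependent histones, mitochondrially encoded genes, fibroblast markers and the remodeler ATPases of the panel. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and at an estimated one, adjusted over all 667 tests of lists and knockdowns. The preset correlation gave 167 called tests and the estimated one 0, since members of a list move together between libraries (estimated correlation 0.774 for histones and 0.756 for ribosomal proteins).

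Profiles of log2 fold changes were compared between knockdowns by Pearson r and covariance across genes, beside 3 simulations of unchanged groups against the same controls and a split of the controls into 9 with odd and 8 with even numbers. The alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors in place of TMM, TMM factors from the noncoding features, no filter on low counts, no batch term, the adjusted table with no batch term, the replicate number as a block, the target's own and control libraries in place of all, and each knockdown library left out in turn. Another 3 were chosen after seeing the data: library sizes without Gm26917 and Gm42418, the share of these gene models as a covariate, and the target's own and control libraries with no batch term. Overlaps were found with GenomicRanges 1.54.1, tables were read with the data.table package (1.17.8) and figures drawn with matplotlib 3.10.9.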

Results

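Newly made RNA was measured by transient transcriptome sequencing (TT-seq), in which cells take up the nucleoside 4-thiouridine (4sU) for a short pulse and the labelled RNA is purified and sequenced. The cells were ES-E14TG2a, a male mouse embryonic stem cell line grown in serum with leukaemia inhibitory factor. Each knockdown used esiRNA, a pool of short interfering RNAs made by enzymatic digestion, against 1 of 29 nucleosome remodeler ATPases, the motor subunits of the complexes that slide, evict or exchange nucleosomes. Labelling and harvest followed 48 hours after transfection. There were 17 control libraries, which received esiRNA against green fluorescent protein, and 68 knockdown libraries, with 3 libraries for 10 targets and 2 for the other 19. Total counts per library ran from 8535217 to 35913536, with a median of 15211296. Noncoding features took 4.32 to 10.2% of them. The gene models Gm26917 and Gm42418, which share sequence with ribosomal RNA, took 8.84 to 57.5% of the gene counts, with a median of 27.1%. The question for every target was which genes and which cis-regulatory elements changed their nascent transcription after its knockdown. Changes are given as log2 fold changes against the controls from edgeR's quasi-likelihood test with a term for the batch, with ± or SE for the standard error, and a change counted as called at an adjusted p under 0.05. Levels are CPM, counts scaled to the library size, with the SD over libraries, and all control levels have n = 17.

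The targeted gene itself was read first in its own knockdown. Smarca5, the ISWI-family ATPase on chromosome 8 (80698507 to 80739497), fell by 0.55 on the log2 scale (SE 0.16, adjusted p = 0.0187), from 157 ± 38.2 CPM in the controls to 110 ± 20.9 CPM (SD, n = 3), and lost its call without replicate 1, where it was -0.35. Chd4, the ATPase of the NuRD complex on chromosome 6 (125095981 to 125130591), went the other way: its nascent RNA was 571 and 802 CPM in the libraries labelled Chd4 knockdown against 361 ± 63.6 CPM in the controls. That is a log2 fold change of 0.90 ± 0.17 (adjusted p = 4.62e-05), higher in both libraries, so a direction drawn from them rests on their label, by which this and every other knockdown is named below. None of the other 27 targeted genes passed the test, with log2 fold changes from -0.41 ± 0.23 for Hltf (adjusted p = 0.74) to 0.46 ± 0.24 for Ep400 (adjusted p = 0.252). Over the panel, 18 targeted genes lay below 0 and 11 above. Of the 39 knockdown libraries that shared a batch with a control, 20 had the targeted gene below that control. Because esiRNA acts on mature RNA and TT-seq reads RNA as it is made, these values do not measure how far each protein was depleted.

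**Figure D1:**
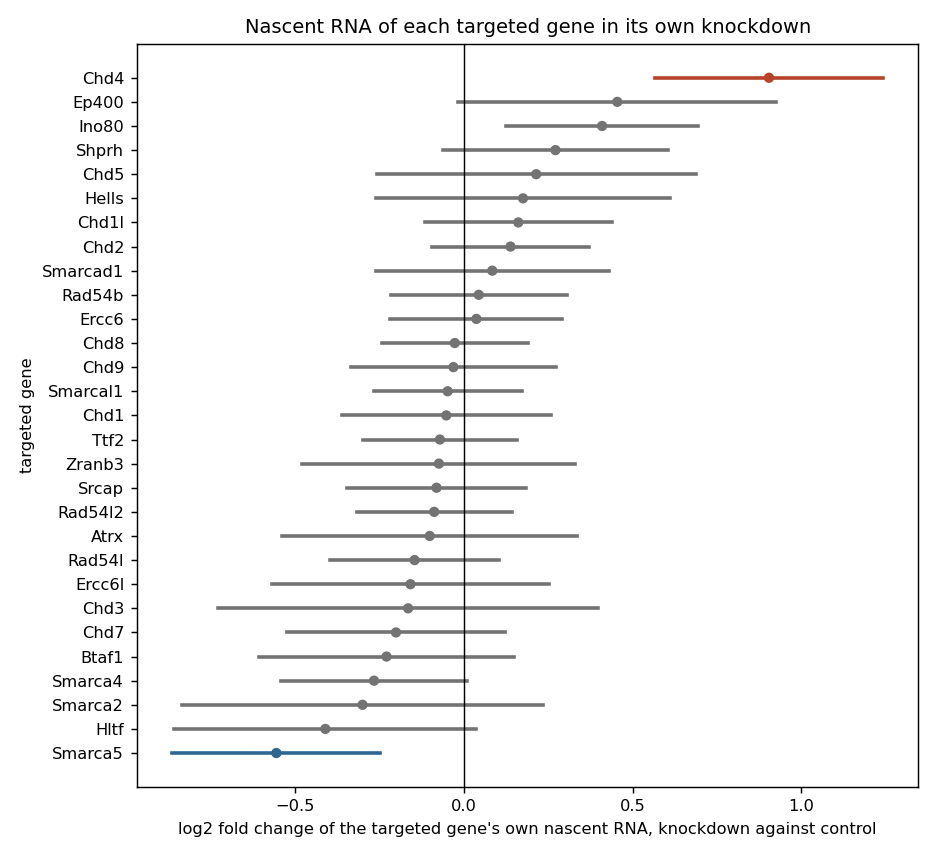
Log2 fold change of each targeted gene in its own knockdown against the controls (x axis, log2), with bars for 95% intervals, 1 point for each of the 29 targets. Chd4 lay at 0.90 and Smarca5 at -0.55, and these 2 were the targets called.

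The panel split into 8 knockdowns with over 100 called genes and 21 with few or none. The libraries labelled Chd4 knockdown had 4416 called genes of 20714 tested, Smarca4 knockdown 2290, Smarca5 2118, Ep400 1613, Srcap 867, Ino80 831, Chd8 280 and Chd1 135. Called noncoding features, of 22076 tested, numbered 3061, 1978, 833, 729, 24, 224, 106 and 38 in the same order. Smarcad1 knockdown had 19 genes and 104 noncoding features.

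**Figure D2:**
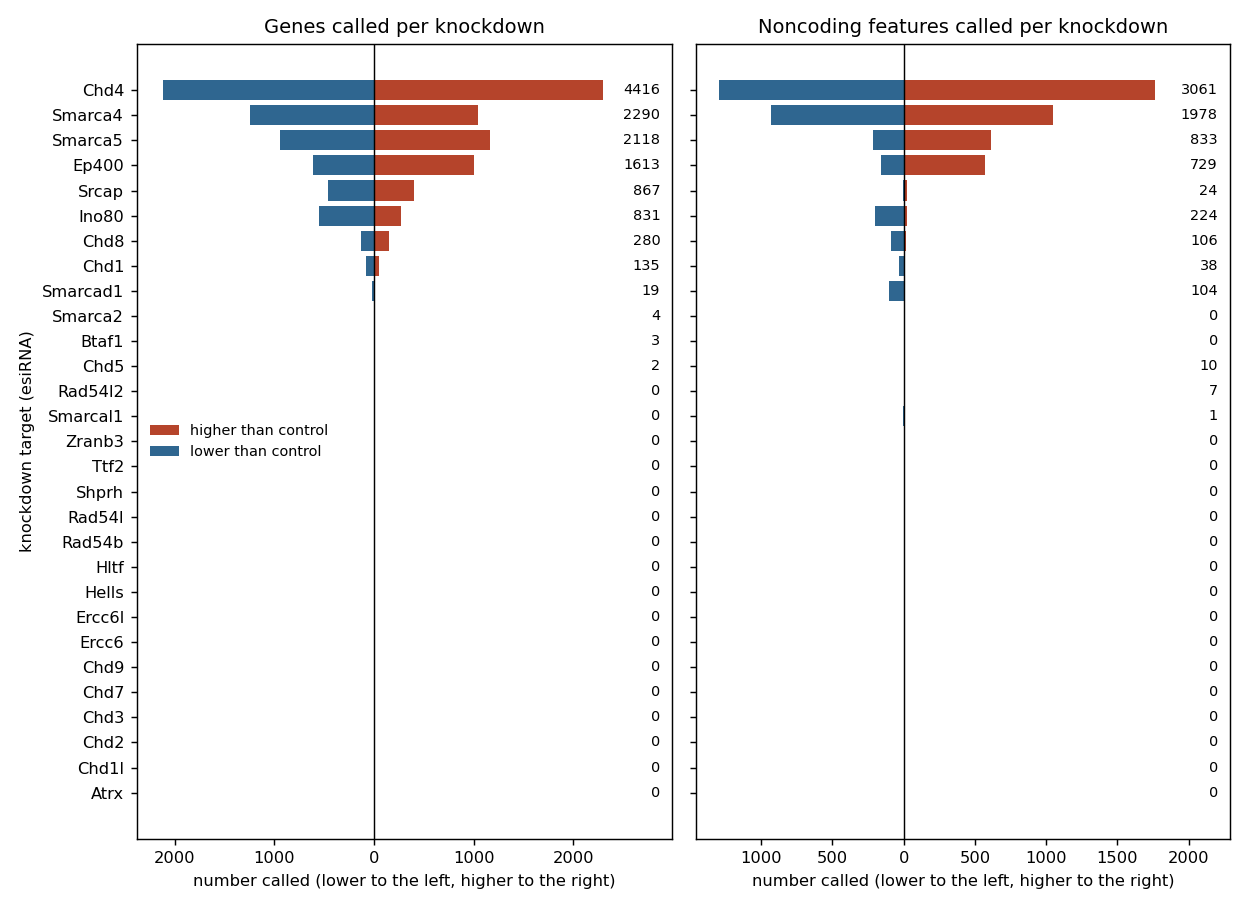
Number of genes (left) and noncoding features (right) called higher and lower in each of the 29 knockdowns, as bars from 0, lower to the left and higher to the right, with totals at the right edge. The libraries labelled Chd4 knockdown lead with 2300 genes up and 2116 down, and 15 knockdowns show 0 called genes and 0 called noncoding features.

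Chd4 was the first of the 3 main comparisons, the targets for which the series also names short depletions. In the libraries labelled Chd4 knockdown, naive pluripotency, neuroectoderm, histone and ribosomal protein genes fell as lists and fibroblast markers rose at the preset correlation, and no list was called at an estimated one. Plb1, a phospholipase on chromosome 5 (32232708 to 32366520), rose most, from 1.81 ± 0.53 CPM to 20.7 ± 2.27 CPM (SD, n = 2), a log2 fold change of 3.71 ± 0.32. Inhbb, the beta B subunit of activin on chromosome 1 (119415465 to 119422248), fell from 52.8 ± 18.9 to 4.34 ± 3.34 CPM (n = 2), which is -3.83 ± 0.40.

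Of the 4416 called genes, 2300 rose and 2116 fell. After Plb1, the largest rises were in Afap1l2 (3.06), an actin filament adaptor, Csmd2 (3.04), Rassf4 (2.92), Abcc2 (2.85), a hepatic export pump, Col7a1 (2.84), the anchoring-fibril collagen, Adcy7 (2.80), an adenylyl cyclase, Cnga3 (2.77), a cone photoreceptor channel, Kcnt1 (2.72), a sodium-activated potassium channel, and Hmcn2 (2.66). Among the largest falls besides Inhbb were those in Skida1 (-3.89), Nkx6-3 (-3.25), a homeobox gene, Cbr3 (-3.23), a carbonyl reductase, Gbx2 (-3.21), a homeobox gene of the anterior hindbrain, Insm1 (-3.20), a transcription factor of neuroendocrine cells, Nefl (-3.17), the light neurofilament, and Polr3gl (-2.89). Standard errors of these genes ran from 0.23 for Kcnt1 to 1.01 for Nkx6-3, and the naming rule required every library to lie on the side of the change. Csmd2, Rassf4, Nefl and Polr3gl overlap another protein-coding gene in the annotation, so their counts are uncertain. Without replicate 1 the call of Nkx6-3 was lost, and those of Klf4, Sox2, Egr2, Ier2, Ddit4, Nop56, Nhp2 and the ribosomal protein genes named next.

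Among the gene lists fixed beforehand, 40 of 52 ribosomal protein genes fell and none rose, with 49 falling when adjusted over the list alone. Rpl35 (-1.12), Rpl27 (-0.99), Rps14 (-0.94) and Rps12 (-0.90) led them, all from families with many pseudogenes that can share reads, and Rpl35 and Rps14 overlap another protein-coding gene. The list test gave an adjusted p of 1.1e-11 (adjusted p = 0.878 with an estimated correlation). Of 42 replication-dependent histone genes, a multicopy family, 27 fell, and 41 when adjusted over the list alone (adjusted p = 5.64e-09, and adjusted p = 0.878 with an estimated correlation). Hist1h3a (-1.89) and Hist1h3g (-1.80) fell most, both of which lost their calls without replicate 1. Immediate early genes, the rapid response to growth signals, fell in 11 of 23 cases and rose in 1, the same counts when adjusted over the list alone (adjusted p = 0.00527, and adjusted p = 0.892 with an estimated correlation). Egr2 (-2.75), Myc (-1.58), Ier2 (-1.51) and Dusp6 (-1.42) were the largest of these.

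Pluripotency genes went down as a list: 5 of 20 naive pluripotency genes fell and 0 rose, with 9 falling when adjusted over the list alone (adjusted p = 0.000866, and adjusted p = 0.878 with an estimated correlation). Nr0b1 (-1.51 ± 0.27), Klf4 (-1.21 ± 0.26), Pou5f1 (-1.20 ± 0.20) and Sox2 (-1.07 ± 0.21) were among them. Neuroectoderm genes fell in 5 of 11 cases, with 5 down and 1 up when adjusted over the list alone (adjusted p = 0.000828, and adjusted p = 0.839 with an estimated correlation), led by Sox1 (-4.20), Gbx2, Pax6 (-2.67) and Ncam1 (-1.11). Fibroblast markers, a list held for other cell types, rose in 6 of 11 cases and fell in 1, as also when adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.839 with an estimated correlation). Their levels stayed low: Col6a1 and Cd44, which lost their calls without replicate 2 and 1, went from 0.0893 to 1.52 CPM and from 0.439 to 2.45 CPM, Col1a1 from 0.835 to 5.69 and Fbln2 from 1.28 to 7.76. In the list of the integrated stress and unfolded protein responses 8 of 26 genes fell and 1 rose, or 10 and 1 when adjusted over the list alone (adjusted p = 0.00975, and adjusted p = 0.885 with an estimated correlation). Phgdh (-1.28) and Shmt2 (-1.17), enzymes of serine and glycine metabolism, fell while Ddit4 (1.17) rose, and Shmt2 overlaps Ndufa4l2. Ribosome biogenesis genes fell in 3 of 30 cases, Nop10 (-0.85), and Nop56 (-0.83) and Nhp2 (-0.66), which overlap Idh3b and Rmnd5b, the same 3 by count when adjusted over the list alone (adjusted p = 0.0363, and adjusted p = 0.878 with an estimated correlation).

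The other lists did not pass the list test in these libraries, though single members did. Formative and primed epiblast genes had 4 up and 8 down of 19 (adjusted p = 0.117), with Foxd3 at -2.48 and Etv4 at -1.39. Targets of p53 had 7 up and 2 down of 24 (adjusted p = 0.126), with Mdm2 at 0.92. Germline genes silenced by DNA methylation had 6 up and 1 down of 21 (adjusted p = 0.162), with Brdt at 2.41, and interferon-stimulated genes 6 up and 0 down of 20 (adjusted p = 0.213). Trophectoderm genes had 5 up and 2 down of 16 (adjusted p = 0.469), with Krt7 at 2.85, and endoderm genes 2 up and 3 down of 17 (adjusted p = 0.573), with Lama1 at -1.57. Imprinted genes had 3 up and 5 down of 27 (adjusted p = 0.209), with Grb10 at -1.32. Mesoderm and primitive streak genes had 2 up and 0 down of 16 (adjusted p = 0.679), with Wnt3 at 2.35. Heat shock genes had 1 up and 5 down of 20 (adjusted p = 0.205), cholesterol biosynthesis 2 and 3 of 24 (adjusted p = 0.403), and glycolysis and hypoxia 3 and 5 of 24 (adjusted p = 0.416). Hox genes had 1 down of 6 (adjusted p = 0.0783), the 2-cell-like list 1 down of 14 (adjusted p = 0.21), and both had 0 when adjusted over the list alone. No mitochondrially encoded gene of 15 was called (adjusted p = 0.256). Among the 29 remodeler ATPases of the panel 4 rose and 2 fell (adjusted p = 0.102), with Chd5 at 2.27 ± 0.23 and Chd3 at 1.94 ± 0.28, the paralogs of Chd4, and Ercc6 at 0.70 ± 0.13.

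Under the Chd4 label noncoding features changed in both directions, with 1764 up and 1297 down of 22076. Intergenic DNase-hypersensitive sites (DHSs), the open sites between genes, had 1255 up and 787 down of 13719, and those inside genes 449 up and 354 down of 6582. Super-enhancers, the long clusters of active sites, had 33 down and 12 up of 176, and promoter antisense regions 123 down and 48 up of 1599. The site DHS__6305 on chromosome 1 (131879444 to 131880593), 12219 bases from the start of Rab29, rose from 4.16 ± 1.35 to 26.2 ± 4.58 CPM (n = 2), a log2 fold change of 2.63. DHS__9579 on chromosome 1, 17364 bases from the start of Parp1, rose by 2.52 on the log2 scale. The largest fall, -4.97, was in a merged block of sites on chromosome 6 (140335600 to 140339269), 84784 bases from the start of Plekha5, followed by -4.42 in a pair of merged sites on chromosome 1 (74363927 to 74365816) that lies over an exon of Catip. Leaving out a library reduced both counts by over 1.5 times: 1674 genes and 919 noncoding features were called without replicate 1, and 2766 and 1078 without replicate 2.

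Chd8 is a CHD-family ATPase, and its own nascent RNA was level with the controls (-0.03 ± 0.11). In the 3 Chd8 knockdown libraries 280 genes were called, 147 up and 133 down. Drc3, which encodes a subunit of the dynein regulatory complex of cilia on chromosome 11 (60353329 to 60394341), rose from 3.69 ± 1.52 to 11.8 ± 0.546 CPM (n = 3), a log2 fold change of 1.82 ± 0.25. Serpine2, a secreted protease inhibitor on chromosome 1 (79794197 to 79861180), rose by 1.37 ± 0.20. Fgf15, a fibroblast growth factor on chromosome 7 (144896531 to 144900953), fell to 4.44 ± 1.45 CPM (n = 3), a log2 fold change of -1.50 ± 0.25.

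The other large rises after Chd8 knockdown were in Pkhd1 (1.32), Smc1b (1.22), the meiotic cohesin subunit, Xrcc4 (1.20), a factor of DNA end joining, Zcwpw1 (1.19), a meiotic histone reader, Tek (1.19), the angiopoietin receptor, Mpzl3 (1.19), Dhx34 (1.18) and Ttll9 (1.14). The largest falls were in Hist2h3c2 (-1.75), Zfp316 (-1.51), Fam187b (-1.40), Trdmt1 (-1.20), an RNA methyltransferase, Hist1h3d (-1.19), Bcl2l14 (-1.16), Prr23a3 (-1.16), Tmem128 (-1.15) and Zfhx4 (-1.12). Both histone genes belong to a multicopy family, and Xrcc4 and Zcwpw1 overlap Tmem167 and Pilra, so these values are uncertain.

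Replication-dependent histone genes fell in 1 of 42 cases after Chd8 knockdown and in 16 when adjusted over the list alone (adjusted p = 2.19e-11, and adjusted p = 0.878 with an estimated correlation). Ribosomal protein genes fell in 3 of 52 cases, Rpl32 (-0.81), Rps4x (-0.65) and Rps25 (-0.60), the first and last over other genes, and in 10 when adjusted over the list alone (adjusted p = 1.26e-11, and adjusted p = 0.878 with an estimated correlation). None of the 15 mitochondrially encoded genes was called over all genes, against 7 down when adjusted over the list alone, with a list median of -1.76 (adjusted p = 1.64e-05, and adjusted p = 0.878 with an estimated correlation). Among p53 targets Bbc3, a pro-apoptotic gene, rose by 0.76, 3 rose when adjusted over the list alone (adjusted p = 0.000274), and among immediate early genes Myc fell by 0.76, with 3 down when adjusted over the list alone (adjusted p = 0.00577). These p53 and immediate early lists gave adjusted p = 0.878 and 0.894 with an estimated correlation. Of the remodeler ATPases Smarca4 (0.62) and Ercc6 (0.54) rose, and 4 rose when adjusted over the list alone (adjusted p = 0.00482, and adjusted p = 0.878 with an estimated correlation).

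Of the 106 noncoding features called after Chd8 knockdown, 88 fell and 18 rose, while all tested noncoding features had a median of -0.18. With factors taken from the noncoding features themselves the split turned, to 70 up and 37 down of 107. A pair of merged sites on chromosome 15 (73679591 to 73681660) rose by 1.19 on the log2 scale and the antisense region at the Wdr26 promoter (chromosome 1, 181210938 to 181213501) by 1.16. The largest falls were -1.80 in merged sites over Hist1h2bg (chromosome 13, 23571872 to 23573261) and -1.70 in DHS__19651 (chromosome 11, 48823319 to 48824468). Leaving out replicate 1, 2 or 3 left 118, 99 and 59 called genes and 23, 14 and 5 noncoding features. Most of the genes named here lost their call without replicate 3.

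Hltf is a SWI/SNF-related ATPase that also carries a ubiquitin ligase domain and works at stalled replication forks. After its knockdown edgeR called 0 genes and 0 noncoding features with 2 libraries. At an unadjusted p under 0.05 there were 1428 genes against 1036 by chance and 1575 noncoding features against 1104, and DESeq2 called 0 and 2. In the list tests ribosomal protein genes had a median of 0.51 and 15 of 52 rose when adjusted over the list alone (adjusted p = 1.51e-17). Replication-dependent histone genes had a median of 1.19 and 20 of 42 rose when adjusted over the list alone (adjusted p = 9.61e-17). Heat shock genes (3 of 20 up, adjusted p = 8.54e-05) and glycolysis genes (4 of 24 up, adjusted p = 0.00226) also had members past the threshold when adjusted over the list alone. Naive pluripotency genes had a median of 0.40 (adjusted p = 7.24e-05) and immediate early genes 0.51 (adjusted p = 4.68e-05), with 0 members past the threshold either way. These 6 lists gave adjusted p = 0.839 for heat shock and adjusted p = 0.878 for the other 5 with an estimated correlation. Noncoding features had a median of 0.23. Without replicate 2, 1 gene and 28 noncoding features were called, and without replicate 1, 0 and 2.

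Smarca4, also named Brg1, is the ATPase of the BAF complexes of embryonic stem cells. After its knockdown 1042 genes rose and 1248 fell, and the largest changes were falls. Emp1, an epithelial membrane protein on chromosome 6 (135362545 to 135383173), went from 9.12 ± 2.86 to 0.476 ± 0.146 CPM (n = 3), a log2 fold change of -4.32 ± 0.28. Xaf1, an interferon-induced gene on chromosome 11 (72301629 to 72313733), fell by 3.90 on the log2 scale (SE 0.39) and Gpx2, a glutathione peroxidase that overlaps Fntb, by 3.76. Ccno, a cyclin-like gene of ciliated cells on chromosome 13 (112987802 to 112990777), rose from 7.72 ± 3.0 to 38.8 ± 20.1 CPM (n = 3), and Tmprss11d (2.09) and Insm1 (2.08) rose with it.

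Interferon-stimulated genes fell in 9 of 20 cases after Smarca4 knockdown and rose in 0, with 10 down and 2 up when adjusted over the list alone (adjusted p = 6.63e-05, and adjusted p = 0.482 with an estimated correlation). Oasl2 (-1.24) and Oas2 (-1.18) were among them, and Mx2 went from 0.264 CPM in the controls to 0 in the knockdown. Hox genes, the patterning genes of the body axis, rose in 3 of 6 cases and in 4 when adjusted over the list alone (adjusted p = 0.000923, and adjusted p = 0.482 with an estimated correlation). These were Hoxd11 (3.50), Hoxd10 (2.61) and Hoxd13 (1.72). The stress-response list had 6 of 26 down, or 8 down and 1 up when adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.895 with an estimated correlation), with Slc7a11 (-4.04), the cystine transporter, and Asns (-1.18), asparagine synthetase, the largest. Neuroectoderm genes had 3 up and 1 down of 11, or 5 and 1 when adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.878 with an estimated correlation), among them Sox1 (1.75), Gbx2 (1.18) and Pax6 (0.77).

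Noncoding features after Smarca4 knockdown had 1051 up and 927 down. Super-enhancers had 29 up and 13 down of 176, and promoter antisense regions 58 up and 28 down of 1599. Calls dropped by over 1.5 times when a library was left out: 1410, 1367 and 1159 genes were called without replicate 1, 2 and 3, and 1188, 1181 and 621 noncoding features. Oasl2 lost its call without any 1 of the libraries, Oas2 without replicate 2 or 3, Hoxd10 and Pax6 without replicate 1 or 2, Hoxd13 without replicate 2, and Mx2 and Gbx2 without replicate 3.

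Smarca5 knockdown gave 1170 genes up and 948 down. Fignl2, on chromosome 15 (101050194 to 101078567), rose from 1.74 ± 0.673 to 8.35 ± 4.24 CPM (n = 3), a log2 fold change of 2.22 ± 0.31, Cdc42ep1 by 1.95, with counts that overlap Lgals2, and Gdf15, a stress-induced cytokine, by 1.78. Abcc2, which rose with the Chd4 label, fell here from 3.37 ± 0.869 to 0.273 ± 0.0682 CPM (n = 3), a log2 fold change of -3.29 ± 0.43. Slc5a4b (-2.91) and Acan (-2.58), the cartilage proteoglycan aggrecan, fell next.

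Replication-dependent histone genes rose in 11 of 42 cases after Smarca5 knockdown and in 32 when adjusted over the list alone (adjusted p = 1.64e-07). Ribosomal protein genes rose in 7 of 52 cases and in 27 when adjusted over the list alone (adjusted p = 2.91e-08). Immediate early genes rose in 8 of 23 cases, among them Egr2 (1.37) and Ier5 (1.01), and in 12 when adjusted over the list alone (adjusted p = 0.000233). Stress-response genes rose in 6 of 26 cases, among them Ddit4 (1.18) and Herpud1 (1.04), and in 9 when adjusted over the list alone (adjusted p = 0.000504). Cholesterol biosynthesis genes rose in 4 of 24 cases, with Mvd, which overlaps another gene, at 0.95, and in 6 when adjusted over the list alone (adjusted p = 0.00152). Endoderm genes rose in 6 of 17 cases by both counts, over all genes and adjusted over the list alone, with Sox17 at 2.03 and Gata6 at 1.38 (adjusted p = 0.0171). Mesoderm genes rose in 5 of 16 cases, with Wnt3a at 1.70, and in 6 when adjusted over the list alone (adjusted p = 0.0285). Germline genes silenced by DNA methylation fell in 4 of 21 cases, with Dazl at -2.01, and in 5 when adjusted over the list alone (adjusted p = 0.00946). Remodeler ATPases fell in 6 of 29 cases, with Chd3 at -1.03 and Hells at -0.65, and in 10 when adjusted over the list alone (adjusted p = 0.000496). Each of these 9 lists had adjusted p = 0.878 with an estimated correlation.

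Noncoding features rose in 615 and fell in 218 cases after Smarca5 knockdown, with a median of 0.17 over all of them, and with factors from the noncoding features the split was 374 up and 373 down of 747. No library of this target shared a batch with a control. With the share of Gm26917 and Gm42418 as covariate 1022 genes and 327 noncoding features were called, and with no batch term 1240 genes. Without replicate 1, 868 genes and 405 noncoding features were called, and without replicate 3, 270 and 14, with Gdf15 and most of the list members named above no longer called.

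Ep400 is the ATPase of the TIP60 complex. In the libraries so labelled Ep400 itself was higher, at 433 and 557 CPM against 319 and 402 in the controls of the same batches (0.46 ± 0.24, not called), so directions rest on the label. There 1003 genes rose and 610 fell. Zan, a sperm membrane protein gene on chromosome 5 (137378637 to 137477064) that overlaps Ephb4, rose by 3.57 on the log2 scale (SE 0.40), Insc, a factor of spindle orientation, by 3.35 and Tmem132d by 3.27. The largest falls were in Mmp23 (-2.24), a metalloproteinase, and in Mir669b (-2.21) and Mir297a-2 (-2.14), 2 microRNA genes inside Sfmbt2 whose counts cannot be told from those of their host.

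Genes of the 2-cell-like state, which mark a rare subpopulation of embryonic stem cells, rose in 11 of 14 cases after Ep400 knockdown and in 12 when adjusted over the list alone (adjusted p = 2.72e-07, and adjusted p = 0.839 with an estimated correlation). Zscan4d rose by 4.99 and Usp17lc by 4.91, both from multicopy families. Zscan4d was 0.457 CPM in replicate 1 and 8.3 CPM in replicate 2. Endoderm genes rose in 7 of 17 cases and in 8 when adjusted over the list alone (adjusted p = 9.26e-06, and adjusted p = 0.839 with an estimated correlation), among them Cubn (3.06), Gata6 (2.38) and Col4a1 (1.81). Germline genes silenced by DNA methylation rose in 5 of 21 cases, with 8 up and 1 down when adjusted over the list alone (adjusted p = 3.35e-05, and adjusted p = 0.839 with an estimated correlation), among them Stra8 (2.63) and Brdt (2.17). Hox genes had 3 of 6 called up by both counts, over all genes and adjusted over the list alone (adjusted p = 0.000897, and adjusted p = 0.482 with an estimated correlation). Immediate early genes rose in 4 of 23 cases by both counts, over all genes and adjusted over the list alone, with Myc at 1.14 (adjusted p = 0.0136, and adjusted p = 0.895 with an estimated correlation). Ribosomal protein genes had 1 of 52 down by both counts, over all genes and adjusted over the list alone (adjusted p = 0.000311, and adjusted p = 0.929 with an estimated correlation). Among the remodeler ATPases Smarca2 rose by 1.92 and Chd7 fell by 0.77.

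Noncoding features after Ep400 knockdown had 570 up and 159 down, of which intergenic sites made up 423 and 112. The calls rested on replicate 2: without it 9 genes and 9 noncoding features were called, against 1423 and 559 without replicate 1, and Insc, Mmp23, Mir669b and most of the named list members lost their calls, while Mir297a-2 and Cubn lost theirs without either library.

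Srcap is the ATPase of a complex that exchanges a histone variant into promoters. After its knockdown 402 genes rose and 465 fell. Egr2, an immediate early transcription factor on chromosome 10 (67535475 to 67542188), rose by 2.75 ± 0.45, with 2.75, 7.95 and 37.4 CPM in the 3 libraries against 2.4 ± 1.3 CPM in the controls. Ccn1, a matricellular protein gene, rose by 1.67 and Pla2g7, a lipoprotein phospholipase, by 1.57. Zfp458 (-1.48), Dnah1 (-1.42), an axonemal dynein, and Stk36 (-1.16), a kinase of ciliary function, fell most.

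Immediate early genes as a list rose in 9 of 23 cases after Srcap knockdown, with Egr3 at 2.68 and Fosb at 1.46, and in 16 when adjusted over the list alone (adjusted p = 5.64e-09, and adjusted p = 0.878 with an estimated correlation). Ribosomal protein genes rose in 2 of 52 cases and in 24 when adjusted over the list alone (adjusted p = 1.48e-10, and adjusted p = 0.878 with an estimated correlation). Trophectoderm genes rose in 3 of 16 cases, with Gata3, which overlaps other genes, at 1.73, and in 7 when adjusted over the list alone (adjusted p = 0.00256, and adjusted p = 0.706 with an estimated correlation). Called noncoding features were 23 up and 1 down, and the median of all tested ones was 0.22. With factors from the noncoding features 0 were called up and 1 down. One library decided the size of these counts: without replicate 3, 10 genes and 0 noncoding features were called, the genes named here lost their calls and Fosb changed sign (-0.20). Without replicate 1 the counts were 266 and 0, and without replicate 2 they were 2347 and 472.

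In the libraries labelled Ino80 knockdown 555 genes fell and 276 rose. Ino80 itself was higher in all 3, at 296, 313 and 316 CPM against 253 ± 31.4 (log2 fold change 0.41, adjusted p = 0.092), so directions rest on the label. Rnf17, a germ cell gene on chromosome 14 (56402581 to 56525032), fell from 34.6 ± 8.04 to 9.0 ± 0.668 CPM (n = 3), a log2 fold change of -1.84 ± 0.21. Clca3b (-2.13) and the homeobox gene Nkx6-3 (-1.84) fell with it, and Nkd2 (1.47), an antagonist of Wnt signalling, Col27a1 (1.26), a fibrillar collagen, and Antxr1 (1.23), an anthrax toxin receptor, rose. Naive pluripotency genes fell in 7 of 20 cases and in 9 when adjusted over the list alone (adjusted p = 5.5e-08, and adjusted p = 0.878 with an estimated correlation). These included Tcl1 (-0.85), Fgf4 (-0.81), Tbx3 (-0.81) and Nanog (-0.69 ± 0.14). Interferon-stimulated genes fell in 3 of 20 cases, with Xaf1 at -1.51, and in 6 when adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.878 with an estimated correlation). Called noncoding features were 202 down and 22 up, with 11 of 176 super-enhancers down and 0 up. With factors from the noncoding features the split was 109 down and 66 up of 175. Without replicate 2, 362 genes and 56 noncoding features were called, and without replicate 3, 166 and 13, where Antxr1, Nkx6-3 and the 4 named pluripotency genes lost their calls.

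Chd1, an ATPase that travels with elongating RNA polymerase, had 53 genes up and 82 down. Rgs9, a regulator of G-protein signalling on chromosome 11 (109225355 to 109298129), had the largest rise (3.69 ± 0.82), with 13.1 and 150.0 CPM in the 2 libraries against 16.1 ± 18.4 CPM in the controls. S100a6 (1.75) and the basement membrane collagen Col4a1 (1.70), which overlaps Col4a2, rose, and Aldh1l2 (-2.92), a mitochondrial folate enzyme that overlaps another gene, Vldlr (-2.72), a lipoprotein receptor, and mt-Nd5 (-2.03), a subunit of complex I that overlaps mt-Nd6, fell. Endoderm genes rose in 2 of 17 cases, Col4a1 and Sparc (0.81), and in 7 when adjusted over the list alone (adjusted p = 4.37e-06, and adjusted p = 0.839 with an estimated correlation). Mitochondrially encoded genes fell in 1 of 15 cases and in 7 when adjusted over the list alone (adjusted p = 6.32e-05, and adjusted p = 0.878 with an estimated correlation). Of the ribosome biogenesis genes Rrp9, which overlaps Parp3, rose by 0.88, and 2 of 30 rose when adjusted over the list alone (adjusted p = 0.00056, and adjusted p = 0.878 with an estimated correlation). In replicate 2, 57.5% of the gene counts lay in Gm26917 and Gm42418, the highest of any library. Called noncoding features were 32 down and 6 up, or 41 and 28 of 69 with factors from the noncoding features. Without replicate 1 a single gene and 0 noncoding features were called, and without replicate 2, 158 and 7. The 135 calls became 1 with no batch term and 438 with DESeq2. Of the genes named here, those that kept their call without replicate 2 were Col4a1 and Aldh1l2.

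Smarcad1 knockdown had more called noncoding features than genes, and all 104 of them fell: 68 intergenic sites, 31 sites inside genes, 3 super-enhancers and 2 promoter antisense regions. The median of all tested noncoding features was -0.165, and with factors from the noncoding features 55 were called, 53 down and 2 up. Of 19 called genes 17 fell, led by Aass (-1.86), an enzyme of lysine breakdown, Tspan2 (-1.52), which overlaps Tshb, and Sstr5 (-1.25), a somatostatin receptor. Spats2l (1.40) on chromosome 1 (57774162 to 57948394) and Plce1 (1.09), a phospholipase C, rose. Without replicate 1, 2 or 3 there were 7, 13 and 12 called genes and 55, 68 and 27 noncoding features. Sstr5 lost its call without any 1 of the libraries, Aass without replicate 1 or 3 and Plce1 without replicate 1.

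**Figure D3:**
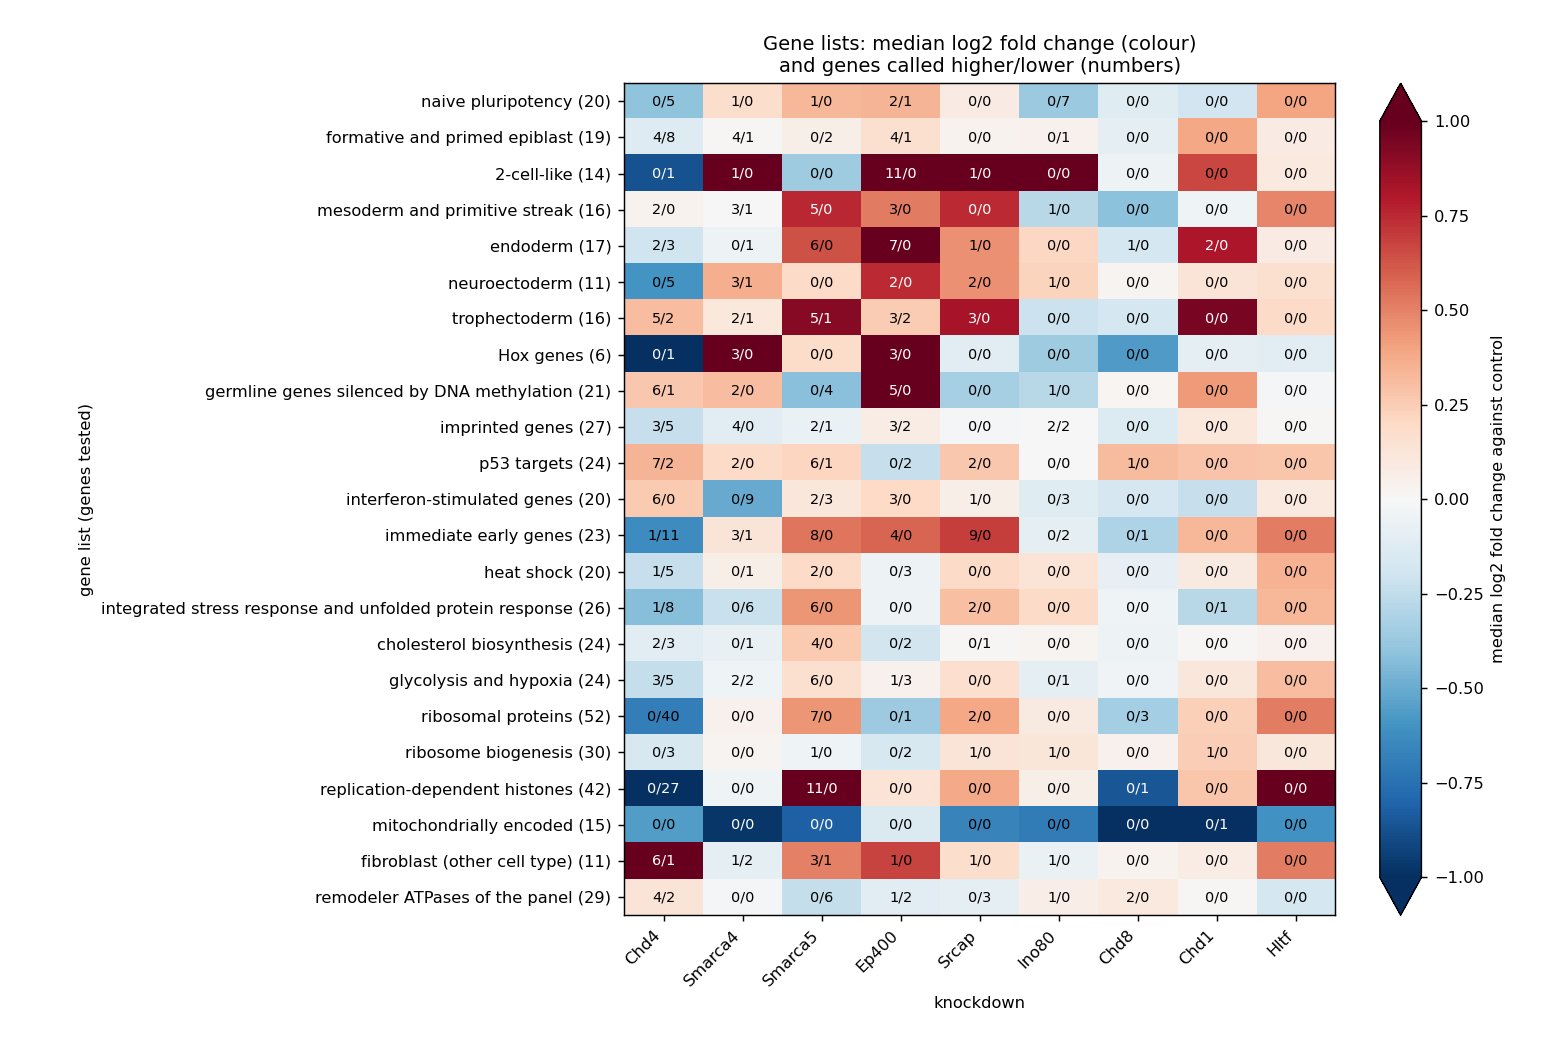
Median log2 fold change of each of the 23 gene lists (rows, with the genes tested in brackets) in 9 knockdowns (columns), as colours that saturate at -1 and 1, with the genes called higher and lower as numbers. Histone genes stand out with a median of -1.38 with the Chd4 label and 1.19 after Hltf knockdown, and the 2-cell-like list with 3.52 after Ep400 knockdown.

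Small sets were called in 5 further knockdowns. After Smarca2 knockdown Usp26 (1.08) and Smad7 (0.57), an inhibitor of transforming growth factor signalling, rose and Emp1 (-0.98) and Gm14154 (-3.03) fell, the last named after its values were seen. Without replicate 1, 0 genes were called, and without replicate 2, 2 genes and 3 noncoding features. After Btaf1 knockdown Stc2 (1.69), a secreted glycoprotein, rose and Sult6b1 (-1.43) and Gtf2a1 (-0.86), a general transcription factor, fell. Without replicate 1 there were 2 called genes and without replicate 2 there were 0, and with RLE size factors 1 gene, a falling one, was left. Chd5 knockdown had 2 called gene models, Gm37376 (3.61) and Gm48622, named after their values were seen, and 10 noncoding features, all up. Without its replicate 1 there were 1 gene and 15 features, and without its replicate 2 there were 0 of both. Rad54l2 knockdown had 7 noncoding features, all intergenic and up, of which 0 were left without either library, and no gene. Smarcal1 knockdown had 1 noncoding feature, DHS__47827 on chromosome 16 (18013208 to 18014357) at -1.20 ± 0.21, named after its value was seen, which lost its call without replicate 1 or 2.

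In 17 knockdowns edgeR called 0 genes, and the counts at an unadjusted p under 0.05 ran from 272 to 3289 where chance gives 1036. They were 3289 for Shprh and 2616 for Smarcal1, of which DESeq2 called 25 and 13. Hltf had 1428, Chd9 1230, Chd2 1125, Rad54b 1017, Hells 993 and Chd1l 873, and DESeq2 called 3 for Chd9, 1 for Chd1l and 0 for the other 4. Rad54l had 773, Atrx 658, Ttf2 633, Ercc6l 580, Ercc6 546, Zranb3 541, Rad54l2 434, Chd7 386 and Chd3 272, with 0 called by DESeq2 in these 9. Noncoding features had 0 calls in 17 knockdowns, and the unadjusted counts there, against 1104 by chance, were 1617 for Shprh, 1575 for Hltf, 1430 for Chd9, 1423 for Btaf1, 1291 for Smarca2, 1279 for Rad54b, 1123 for Chd2, 1097 for Atrx, 959 for Chd1l and between 459 for Chd3 and 834 for Rad54l in the others. DESeq2 called 14 noncoding features for Shprh, 2 each for Atrx, Ercc6l and Hltf, 1 each for Chd1l, Ercc6, Hells and Ttf2, and 0 for the rest. Leaving out replicate 2 brought 44 genes and 14 noncoding features for Chd9, 3 genes for Chd2, 3 noncoding features for Rad54l and 1 each for Ercc6 and Shprh, and leaving out replicate 3 brought 2 genes for Rad54b. Replication-dependent histone genes had a median of -0.96 after Smarcal1 knockdown, where 30 of 42 fell when adjusted over the list alone (adjusted p = 1.29e-16, and adjusted p = 0.878 with an estimated correlation).

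Calls were then compared by gene. Of the 20714 tested genes 11877 were called in no knockdown, 6036 in 1, 2047 in 2, 596 in 3, 133 in 4, 22 in 5 and 3 in 6. In 3 simulations of unchanged groups against the same controls no gene was called in more than 2. No gene was called in 10 or more, which says little where 8 knockdowns had 100 or more called genes. Ccnd2 was called in 6: down for the Chd4 label (-2.19), Smarca4 (-2.25), Chd8 (-0.83) and Ino80 (-0.76), up for Ep400 (1.52) and Srcap (0.63). Pwwp2b rose for the Chd4 label (1.07), Srcap (0.63) and Smarca5 (0.55) and fell for Smarca4 (-1.46), Chd8 (-0.71) and Ino80 (-0.63). Chd8 and Ino80 share batches 6, 13 and 22, only 13 with a control, so they are not independent. Csmd2, Gcnt4, Ttll9, Zcwpw1, Grk3 and Ppm1h, also by the rule, were called in 5.

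Fold changes were then compared between targets across genes, which are not independent replicates, for all 406 pairs. The median Pearson r was 0.083, against 0.08 in the simulations, where only the shared controls act. The profile with the Chd4 label ran against that of Smarca4 knockdown, with r = -0.155 where the simulations gave 0.156 and a covariance of -0.0723 against 0.0224. With the controls split between the 2 comparisons r was -0.192. Genes called in both went opposite ways in 593 cases, where independent lists would give 245, and the same way in 242, where they would give 243. Against Smarca5 knockdown r was -0.167 (simulated 0.202; covariance -0.0818 against 0.0321; -0.213 with split controls), with 483 genes opposite (independent lists 225) and 173 the same way (227). Smarca5 and Srcap knockdown went together, with r = 0.364 (simulated 0.273; covariance 0.1 against 0.0355; 0.241 with split controls), and 185 genes were called in both the same way (independent lists 44, which leave out the shared controls) against 3 opposite (44.7). Both replicates 3 share a control-free batch, and without them r was 0.169. Hltf and Smarca5 had r = 0.362 (simulated 0.131), and Shprh and Smarcal1, which also share one, 0.44 (simulated 0.228).

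**Figure D4:**
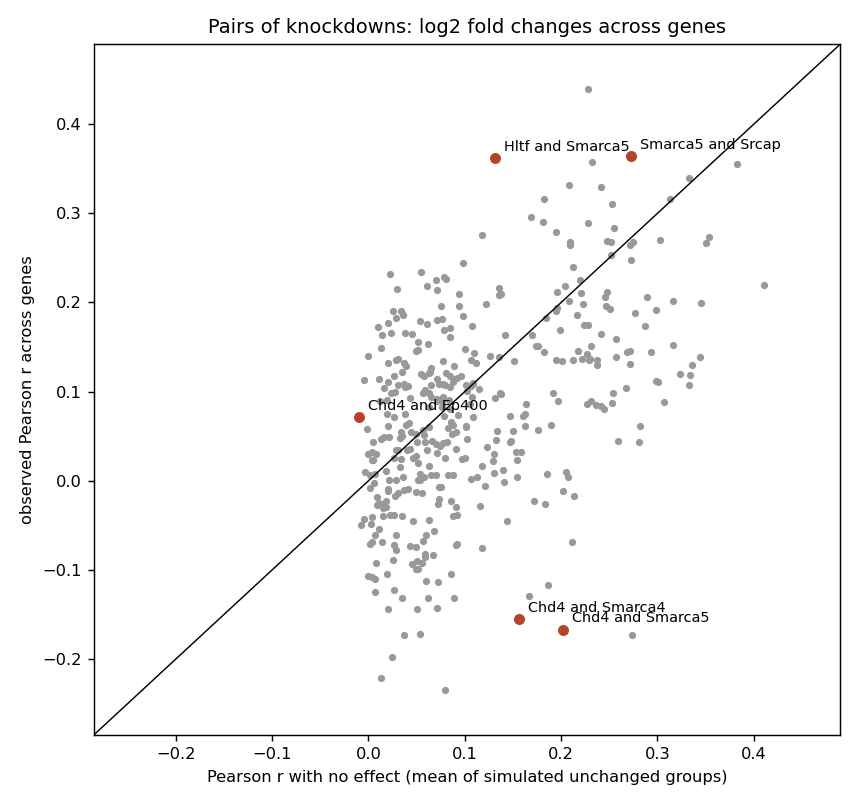
Pearson r of log2 fold changes across genes for each pair of targets (y axis) against the value simulated for unchanged groups with the same controls (x axis), 1 point per pair and a line where both are equal. The pairs of the Chd4 label with Smarca4 (-0.155) and with Smarca5 (-0.167) lie below 0 where the simulations lie above it.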

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

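The limit of 50 times the chance share in the next paragraph, the test of the library with the highest share of ribosomal-like counts, and the tests of noncoding scaling were chosen after the results were seen. The tests of a swap, of a general shift and of the share as a covariate were fixed before their results.

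Some features that no comparison of the report used lay above the controls in the adjusted values. The authors' adjusted table holds 19040 promoter antisense features that the raw table lacks, of which 1991 had a control mean of at least 10. In 149 of these all 3 Smarca4 knockdown libraries lay above all 17 controls (7.48%), in 235 all 3 Smarca5 libraries (11.8%) and in 90 all 3 Srcap libraries (4.52%), where chance would give 0.0877%. Targets with 2 libraries, for which chance gives 0.585% and none met the limit, had shares up to 16.2% for Btaf1, 14.4% for Hltf and 13.1% for Atrx, which had few or no calls. Below all controls lay 144 of the 1991 for Chd8 (7.23%, 3 libraries) and 442 for the Chd4 label (22.2%, 2 libraries). Adjusting itself raised such shares: for the promoter antisense features in both tables they were 6.72%, 11.2% and 3.49% of 803 after it, and 2.42%, 0.363% and 1.93% of 827 before it.

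Nascent Chd4 RNA was higher, not lower, in both libraries labelled Chd4 knockdown. A swap of 1 of them with a library of another target was tested by the similarity of their 2 profiles, which correlated at r = 0.58 across genes, while the highest r of either with another target was 0.263, with Smarcal1. That argues against a swap of 1 library. A general shift of genes like Chd4 was tested on the 200 genes nearest to it in level and length, of which 99.5% had a lower log2 fold change, with a median of -0.042 over the 200, which argues against that shift. A wrong label on both libraries stays open, as does a rise of transcription when the mature RNA or the protein is lost, which may act as feedback and was not tested.

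The Chd1 knockdown held the library with the lowest TMM factor, 0.588, and the highest share of Gm26917 and Gm42418 counts, 57.5%. If that share were the whole cause of the 135 calls, a covariate for it would end them, yet 130 were still called among 177 in all. Differences between the controls that follow the share had the sign of the Chd1 change in 82.2% of the called genes. Over all tested genes that was 63.9%. They may therefore add to the changes, and the covariate cannot settle how much. Without replicate 2, the library in question, the median ratio to the fold changes with both was 0.952, and all 135 kept their sign. The calls themselves moved more, to 158 without replicate 2 with 23 of the 135 among them, and to 1 without replicate 1. With no batch term 1 gene was called, with own and control libraries besides 0, and with DESeq2 438. Batch 10 holds only replicate 1 and 1 control, a comparison that the batch term imposes and that may give most calls. A Chd1 effect is also open and rests on these 2 libraries.

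Noncoding features were called mostly in 1 direction in several knockdowns, and 4 of these were weighed: Chd8, Ino80, Smarcad1 and Srcap. A shift of all noncoding features against the genes would give such calls by scaling alone, so they were called again with factors from the noncoding features. Of those not weighed, Smarca5 went from 615 of 833 up to 374 of 747, Chd1 from 32 of 38 down to 41 of 69, Ep400 from 570 of 729 up to 512 of 747, Chd5 from 10 of 10 up to 17 of 17 and Rad54l2 from 7 of 7 up to 14 of 14. In the weighed ones 34.6% of calls kept the main direction for Chd8, 62.3% for Ino80 and 0% for Srcap (1 call, opposite). A shift of the whole class is a likely part of those patterns. For Smarcad1 96.4% of 55 calls were still falls, which argues against scaling as the whole cause there. Without 1 library 27 to 68 were left. Chd8, Ino80, Smarcad1 and Smarcal1 share control-free batches 6 and 22 and had noncoding medians of -0.184 to -0.127. Chd9 shares them too, with 0.017. Whether shifts are biological or come from these batches, unspliced or background reads was not tested.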

How the results depend on the processing

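The settings compared here were those planned, except the 3 named in the processing as chosen after seeing the data. A count is called stable below when it stayed within 1.5 times the reported one, or was 0 and stayed 0. Many knockdowns had no calls, so counts of 0 make up much of the stable ones in several settings. The cause of a change was not tested unless one is given. The counts moved little with RLE size factors, where 29 of 30 gene counts and 28 of 29 noncoding counts were stable. Exceptions were Btaf1 with 1 gene and Srcap with 59 noncoding features. Library sizes without Gm26917 and Gm42418 kept 28 of 29 gene counts, all but Btaf1 with 1 gene, and as many noncoding counts, all but Zranb3 with 1 feature. Of the genes called with the Chd4 label 4222 were called again in the same direction with RLE, and 2273 of those after Smarca4 knockdown. Of the named genes and features, 411 of 420 kept direction and side of the threshold with RLE and 404 of 417 with DESeq2, and the rest lost the call but not the direction. With no batch term 261 of 420 did and 151 lost the call, with own and control libraries and no batch term 253 and 159, and with the share as covariate 362 and 53. With the replicate block 45 of 354 did and 300 lost the call.

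DESeq2 kept 22 of 30 gene counts and 13 of 29 noncoding counts. Its other gene counts were 438 for Chd1, 1 for Chd1l, 0 for Chd5, 490 for Chd8, 3 for Chd9, 25 for Shprh, 43 for Smarcad1 and 13 for Smarcal1. Noncoding features called by it numbered 2 for Atrx, 149 for Chd1, 1 for Chd1l, 0 for Chd5, 447 for Chd8, 1 for Ercc6, 2 for Ercc6l, 1 for Hells and 2 for Hltf. Ino80 had 508, Rad54l2 14, Shprh 14, Smarcad1 216, Smarcal1 84, Srcap 151 and Ttf2 1. The changed genes were largely the same where many were called, with 4216 of 4416 for Chd4 and 124 of 135 for Chd1 called by both tools in the same direction.

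Without the low-count filter more features entered the test and only 4 of 30 gene counts and 1 noncoding count were stable. Gene counts became 232 for Atrx, 248 for Btaf1, 503 for Chd1, 181 for Chd1l, 98 for Chd2, 114 for Chd3, 122 for Chd5, 133 for Chd7 and 1095 for Chd8. Chd9 had 352, Ercc6 114, Ercc6l 123, Hells 96, Hltf 322, Ino80 1293, Rad54b 153, Rad54l 75 and Rad54l2 88. Shprh had 862, Smarca2 182, Smarcad1 450, Smarcal1 904, Srcap 1465, Ttf2 132 and Zranb3 530. Noncoding counts became 1466 for Atrx, 1154 for Btaf1, 308 for Chd1, 1175 for Chd1l, 325 for Chd2, 823 for Chd3, 4974 for Chd4, 972 for Chd5 and 1396 for Chd7. Chd8 had 2561, Chd9 1801, Ercc6 416, Ercc6l 671, Hells 195, Hltf 844, Ino80 2347, Rad54b 695 and Rad54l 203. Rad54l2 had 505, Shprh 1539, Smarca2 1055, Smarca4 3008, Smarca5 3350, Smarcad1 2542, Smarcal1 2737, Srcap 2376 and Ttf2 905. Zranb3 had 3057. Genes called in 10 or more knockdowns rose from 0 to 77. Among the genes that pass the filter, Chd4 had 3954 calls in this setting, of which 3609 were among the 4416, Btaf1 had 116 and Smarcad1 121, so filtered genes made part of the rise, and the cause of the rest was not tested.

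Without a batch term 19 of 30 gene counts and 22 of 29 noncoding counts were stable. The other gene counts were 1 for Btaf1, 1 for Chd1, 1 for Chd2, 0 for Chd5, 141 for Chd8, 2749 for Ep400, 1 for Rad54b, 0 for Smarca2 and 1240 for Smarca5. Smarcad1 had 12 and Smarcal1 2. The other noncoding counts were 0 for Chd1, 0 for Chd5, 8 for Chd8, 1394 for Ep400, 366 for Ino80, 35 for Smarcad1 and 280 for Srcap. Of the genes called after Chd1 knockdown 1 was called again, and of those with the Chd4 label 2988. After Ep400 knockdown Chd2 went from -0.42 to 0.033. With each target's own and control libraries and no batch term it took the same value, 0.033. Gene counts there were 0 for Btaf1, 0 for Chd1, 1 for Chd2, 0 for Chd5, 83 for Chd8, 5 for Chd9, 1 for Rad54b, 3 for Shprh and 0 for Smarca2. Smarca5 had 827, Smarcad1 10 and Smarcal1 2. Noncoding counts there were 0 for Chd1, 0 for Chd5, 6 for Chd8, 4 for Chd9, 544 for Smarca5, 24 for Smarcad1 and 202 for Srcap.

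Own and control libraries with the batch term left 1 residual degree of freedom for 13 targets. For 16 targets this setting was not run, as it left no residual degree of freedom, and for Chd1l, Smarca5 and Zranb3 among them the change could not be estimated either. Where it was run, genes called numbered 78 for Chd1, 2 for Chd2, 8 for Chd3, 57 for Chd5, 709 for Ep400, 35 for Ercc6, 23 for Ercc6l, 14 for Hells and 20 for Rad54b. Rad54l had 1028, Smarca4 4172 and Srcap 4. Noncoding features called there numbered 63 for Chd1, 2 for Chd3, 22 for Chd5, 282 for Ep400, 12 for Ercc6, 15 for Ercc6l, 5 for Hells, 9 for Rad54b and 203 for Rad54l. Smarca2 had 3 and Srcap 0. After Srcap knockdown Fosb went from 1.46 to -0.162 and Tagln from 1.45 to -0.06.

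The authors' adjusted values with no batch term gave more calls in every knockdown. Gene counts were 538 for Atrx, 2069 for Btaf1, 4574 for Chd1, 1112 for Chd1l, 1049 for Chd2, 29 for Chd3, 8672 for Chd4, 564 for Chd5 and 104 for Chd7. Chd8 had 3949, Chd9 874, Ep400 8023, Ercc6 55, Ercc6l 334, Hells 334, Hltf 3664, Ino80 4750 and Rad54b 355. Rad54l had 244, Rad54l2 173, Shprh 4179, Smarca2 818, Smarca4 6357, Smarca5 8598, Smarcad1 986, Smarcal1 2875 and Srcap 5657. Ttf2 had 439 and Zranb3 1847. Noncoding counts were 1173 for Atrx, 1809 for Btaf1, 1865 for Chd1, 401 for Chd1l, 1159 for Chd2, 160 for Chd3, 7800 for Chd4, 741 for Chd5 and 852 for Chd7. Chd8 had 3689, Chd9 785, Ep400 6818, Ercc6 91, Ercc6l 643, Hells 576, Hltf 3463, Ino80 3113 and Rad54b 460. Rad54l had 299, Rad54l2 722, Shprh 1258, Smarca2 540, Smarca4 5769, Smarca5 6210, Smarcad1 1837, Smarcal1 1851 and Srcap 4393. Ttf2 had 358 and Zranb3 2735. Genes called in 10 or more knockdowns numbered 99. This setting removes the batch from the counts without charging the test for it, so its excess is partly built in. It called 4408 of the 4416 genes of the libraries labelled Chd4 knockdown in the same direction, and 135 of the 135 of Chd1.

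With TMM factors from the noncoding features, which leave the genes as they are, noncoding counts moved to 69 for Chd1, 17 for Chd5, 14 for Rad54l2, 55 for Smarcad1, 3 for Smarcal1 and 1 for Srcap. Directions moved further: Chd8 went from 18 up and 88 down to 70 up and 37 down, Ino80 from 22 and 202 to 66 and 109, and Smarca5 from 615 and 218 to 374 and 373. For Chd1 they went from 6 and 32 to 28 and 41, for Srcap from 23 and 1 to 0 and 1, and for Smarcal1 from 0 and 1 to 2 and 1. Gene directions moved by over 10 points of a percentage in Btaf1 alone, from 1 up and 2 down to 0 and 1 with RLE and without Gm26917 and Gm42418. These factors shift the median noncoding feature by -0.196 to 0.198 on the log2 scale, over 0.1 in size for 13 targets, whereas RLE shifts it by -0.024 to 0.032. With the share of Gm26917 and Gm42418 as covariate, Smarca5 went to 1022 genes and 327 noncoding features, Srcap to 7 noncoding features and Chd5 to 19. With a correlation estimated from the data, camera called 0 of the 667 list tests against 167 at the preset one.

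The replicate number as a block beside the batch term, as in a paired design, could use 70 libraries with 3 controls among them and 18 residual degrees of freedom. In it 1 term was aliased and dropped, and the Ep400 change was not estimable. Numbers do not pair these libraries: profiles of the same number had a median r of 0.019 over 915 pairs, against -0.012 for other numbers, while those of the same batch had 0.113 over 120 pairs. Genes called with the block were 1 for Atrx, 3 for Chd1, 1 for Chd1l, 1 for Chd2, 2 for Chd3, 205 for Chd4, 1 for Chd5, 4 for Chd7 and 1 for Chd8. Chd9 had 4, Ercc6 1, Hells 1, Hltf 1, Ino80 4, Rad54b 2, Rad54l 2, Rad54l2 2 and Shprh 1. Smarca2 had 2, Smarca4 20, Smarca5 4, Smarcad1 2, Smarcal1 2, Srcap 6, Ttf2 3 and Zranb3 2. Noncoding features called with the block were 7 for Atrx, 4 for Btaf1, 3 for Chd1, 4 for Chd1l, 5 for Chd2, 7 for Chd3, 24 for Chd4, 3 for Chd5 and 3 for Chd7. Chd8 had 8, Chd9 9, Ercc6 5, Ercc6l 6, Hells 5, Hltf 2, Ino80 4, Rad54b 3 and Rad54l 3. Shprh had 3, Smarca2 4, Smarca4 7, Smarca5 5, Smarcad1 7, Smarcal1 3, Srcap 8, Ttf2 5 and Zranb3 7. In that fit Aldh1l2 after Chd1 knockdown reversed to 2.127, Vldlr to 1.094 and Hspa8 after Smarca5 knockdown to -0.004. With 3 controls in place of 17, fewer calls follow from the construction.

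Leaving out a knockdown library makes a group of 2 a single library, which is then assumed to vary like the other groups. Of 68 gene counts 40 were stable, and 34 noncoding counts. Where one moved, the lowest and highest gene counts were 0 to 2 for Btaf1, 1 to 158 for Chd1, 0 to 3 for Chd2, 1674 to 2766 for Chd4, 0 to 1 for Chd5, 59 to 118 for Chd8, 0 to 44 for Chd9, 9 to 1423 for Ep400 and 0 to 1 for Hltf. Ino80 had 166 to 626, Rad54b 0 to 2, Smarca2 0 to 4, Smarca4 1159 to 1410, Smarca5 270 to 2255, Smarcad1 7 to 13 and Srcap 10 to 2347. The lowest and highest noncoding counts were 0 to 7 for Chd1, 919 to 1078 for Chd4, 0 to 15 for Chd5, 5 to 23 for Chd8, 0 to 14 for Chd9, 9 to 559 for Ep400, 0 to 1 for Ercc6, 2 to 28 for Hltf and 13 to 166 for Ino80. Rad54l had 0 to 3, Rad54l2 0 to 0, Shprh 0 to 1, Smarca2 0 to 3, Smarca4 621 to 1188, Smarca5 14 to 698, Smarcad1 27 to 68, Smarcal1 0 to 1 and Srcap 0 to 472. Most of the Ep400 calls ended without replicate 2 (9 genes left), and most of those of Srcap without replicate 3 (10 left), of Smarca5 without replicate 3 (270 left) and of Chd1 without replicate 1 (1 left). Tnfrsf10b in Ep400 knockdown ranged from -1.398 without replicate 1 to 0.005 without replicate 2, and Fosb in Srcap knockdown from -0.201 without replicate 3 to 2.138 without replicate 2. Of the 1066 values of named genes and features, 586 kept direction and side, 464 lost the call and 2 reversed.

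The planned settings for depleted lines, and the comparison of knockdown with depletion among genes with an average log2 CPM of at least 3, were not run. Depth and group size limit what can be called: at 2 libraries the simulated fit, with a typical spread for every gene, recovered 58.2% of genes changed by a fold of 2.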

Other observations

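Of the tests below, those of opposite and shared changes between knockdowns and the splits of the Smarca4 and Smarca5 libraries were chosen after the results were seen, and the rest before.

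Some gene lists moved in knockdowns with few or no called genes, each at the preset correlation and none at an estimated one. After Smarcal1 knockdown 6 of 14 2-cell-like genes rose when adjusted over the list alone, with a median log2 fold change of 1.66 (adjusted p = 1.14e-05, and adjusted p = 0.878 with an estimated correlation). In the same libraries 8 of 20 naive pluripotency genes fell when adjusted over the list alone, with a median of -0.30 (adjusted p = 4.04e-05, and adjusted p = 0.878 with an estimated correlation). Formative and primed epiblast genes rose in 7 of 19 cases after Chd9 knockdown and in 6 after Smarca2 knockdown when adjusted over the list alone, with medians of 0.44 and 0.42 (adjusted p = 5.02e-06 and 6.5e-06, and adjusted p = 0.482 with an estimated correlation for both). After Hells knockdown 3 of 24 p53 targets rose when adjusted over the list alone, with a median of 0.30, and germline genes had a median of 0.32 with 1 of 21 called (adjusted p = 2.21e-05 and 5.75e-05, and adjusted p = 0.839 with an estimated correlation for both).

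Called intergenic features may follow the gene with the nearest start. Of 1131 such pairs in the libraries labelled Chd4 knockdown 65.6% had the same sign, where 1000 shuffled pairings gave 44.4 to 52.7%. After Smarca4 knockdown it was 76.8% of 714 (shuffled 44 to 56%), after Smarca5 knockdown 72.6% of 358 (49.2 to 62.6%) and after Ep400 knockdown 67.9% of 330 (44.8 to 59.4%). Reads that run past gene ends could give the same pattern, so features over 10 kb from every protein-coding gene were tested apart. There the shares were 64.1% of 532 for Chd4 (shuffled 41.2 to 55.5%), 71.7% of 396 for Smarca4 (42.9 to 58.1%) and 62.3% of 162 for Smarca5 (37.7 to 59.9%), above the shuffled range. For Ep400 it was 62.1% of 177, within the shuffled range of 44.1 to 65.5%. The order of events between feature and gene was not tested.

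NuRD, whose ATPase is Chd4, and the complexes of Smarca4 and Smarca5 may act in opposite directions on shared genes. Genes called in both went opposite ways in 593 cases for Chd4 and Smarca4 and in 483 for Chd4 and Smarca5, where independent lists would give 245 and 225. Chd4 and Ep400 did not follow this: 221 genes went opposite ways (independent lists 170) and more, 298, the same way (173). The direction rests on the Chd4 label, which stays open.

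Smarca5 and Srcap knockdown shared 185 genes called the same way (independent lists, which leave out the shared controls, 44). Across genes r was 0.364, and 0.273 in simulated unchanged groups with the same controls. Those had at most 2 called genes each, and with split controls r stayed positive, which argues against shared controls as the whole source. Both replicates 3 lie in 1 control-free batch. Without them r was 0.169, below 0.273, and Srcap had 10 called genes. The shared batch may give most of the likeness, though smaller groups were not simulated.

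For each of the 10 targets with 3 libraries, 20 other splits were drawn in which 3 of its own and the 17 control libraries took its place, and with the real split they make 21. The real split alone reached its count, 1 of 21, in these cases. That is the smallest share 21 splits can give, and over 20 such tests about 1 would reach it by chance, so chance is excluded only where the other splits stayed far below. For genes the cases at 1 of 21 were Smarca4 (2290, highest other 819), Smarca5 (2118, highest other 1), Ino80 (831, highest other 264), Chd8 (280, highest other 57) and Smarcad1 (19, highest other 0). Smarca2 (4, highest other 1) also was 1 of 21, with few calls. For noncoding features they were Smarca4 (1978, highest other 707), Smarca5 (833, highest other 2), Ino80 (224, highest other 47), Chd8 (106, highest other 4) and Smarcad1 (104, highest other 2). The highest other splits of Smarca4, Ino80 and Chd8 held 2 of the target's own libraries. For Srcap chance was not excluded either: 2 of 21 splits called as many genes (867, highest other 1091) and as many noncoding features (24, highest other 75). The other of these splits held 2 Srcap libraries and 1 control. For Smarcal1 2 of 21 reached the 1 noncoding feature (highest other 2). Where 0 were called all 21 splits reach the count by construction, so the splits decide nothing for genes of Chd9, Rad54b and Smarcal1 (highest other 1 in each) and noncoding features of Chd9 and Smarca2 (highest other 1) and Rad54b (highest other 3).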
